A study of Homo sapiens with 6 samples.

How the data were processed

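Kidney organoids grown from WA09 (H9), an established human embryonic stem cell line, were compared with and without added VEGF165, a secreted factor that acts on endothelial cells. Per the labels, cells were plated in mTeSR1 with 10 µM Y27632, changed to mTeSR1 with 1.5% GelTrex at 16 hours and to 12 µM CHIR99021 at 60 hours, and kept in Advanced RPMI with B27 supplement from 96 hours. VEGF165 was used at 50 ng/ml and organoids were harvested on day 21. For single cells, the organoids of a single well were dissociated at 4 °C with a cold-active protease and run on Drop-seq at 200000 cells per ml. Drop-seq captures each cell with a barcoded bead in a droplet. The series holds 4 Drop-seq libraries (2 with VEGF and 2 without) and 2 bulk RNA-seq libraries (1 with VEGF and 1 without). The labels do not describe the bulk extraction separately. The labels give the wells as separate collections, so the spread between libraries is a spread between wells. The identifiers of the libraries run from A to D. Libraries A and B are VEGF replicate 1 and no VEGF replicate 1, libraries C and D are the second replicates, and the bulk libraries carry the identifiers A and B too. No paired analysis was made, because the labels do not say that libraries with neighbouring letters shared a plating or a run.

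The deposited Drop-seq tables hold whole-number counts per gene and cell barcode, 3000 barcodes in each table, with no normalization by the authors found in the values. The labels name FastQC 0.11.4, Picard 1.115 and build GRCh38 for these tables. They do not state the aligner, the rule that chose 3000 barcodes, or whether a count is a molecule; Drop-seq tables normally count unique molecular identifiers. The deposited bulk tables hold read counts per Ensembl gene, with 5 summary lines that name no gene. The labels name FastQC 0.11.4, STAR 2.5.2, HTSeq with the version string 2.20.2, and edgeR. The bulk tables had 58051 gene rows, of which 98.1% were given a symbol from the reference annotation. Single-cell genes were matched to bulk genes by symbol, or by an older symbol where the reference gave one. It gave none for MYL11, so MYLPF, the same gene, was left unmatched and is missing from the bulk muscle list.

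Barcodes with at least 500 detected genes and at most 25% mitochondrial counts were kept as cells. This kept 2217 and 2842 barcodes with VEGF and 2710 and 2977 without. Counts were scaled to the same total per cell and log-transformed in scanpy 1.11.5. The 2000 most variable genes, chosen within libraries, gave 30 principal components and a graph of 15 neighbours. Leiden clustering (python-igraph 0.11.9) at resolution 0.8 gave 19 clusters, numbered from 0. No batch correction was applied. A cell type marker counted for a cluster when it was detected in at least 10% of its cells and was at least 2-fold higher than in all other cells with 20 CPM added to each. A cluster took the name of a cell type with at least 3 such markers and more than any other type, unless another type had more markers among the 10 leading genes, which left cluster 7 without a name. A condition was added after the clusters had been seen: a marker of that type among the 10 leading genes, or at least 5 markers. It left clusters 4 and 18 without a name. Classes are therefore called podocyte-like and so on, and clusters that met no rule are called unnamed.

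Counts were summed over the kept cells of each library, and over the cells of each class in each library. Genes were tested in edgeR 4.0.16 with the quasi-likelihood test, TMM factors and filterByExpr, with library as the unit (n = 2 against 2). Classes with at least 20 cells in every library were tested. An adjusted p (Benjamini-Hochberg) under 0.05 was called. Log2 ratios are VEGF over no VEGF and their errors are standard errors of the fit. CPM use library sizes scaled by TMM factors and are given as mean ± SD over 2 libraries. Shares of classes were tested with edgeR on cells per class and library with a common dispersion, over 9 classes, and separately over 19 clusters. The endothelial-like share, fixed as the first question, has an exact permutation test over the 4 libraries. Its smallest possible p is 0.333. Gene lists (15 of cell types and 7 of programs) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry. The difference between a class and the mean of the other classes was tested as a contrast in one edgeR fit over all class sums, which was chosen after the class results had been seen, as were the tests per cluster and the merging of barcodes.

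Bulk values were scaled with TMM, 1 CPM was added to each, and the log2 ratio was taken. With 1 library per group there is no p. Exact (Clopper-Pearson) 95% intervals give the counting error of each ratio. A list's median was placed among the medians of 10000 random lists of the same size matched on expression in 20 bins. Genes of a random list were drawn independently, so this range is too narrow for lists whose genes move together. Counting intervals and limits cover counting error only, not the spread between libraries. Reads of the bulk libraries carry no molecular identifiers, so copies of 1 molecule count separately. The bulk intervals may therefore be too narrow even for counting error. For cell shares the intervals are exact (Clopper-Pearson) 95% intervals over cells. They take each kept barcode as 1 cell, so they are too narrow where 1 bead was counted as several cells. Where a group held 0 counts, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its exact counting interval.

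The lists, the cell filter, the tests and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes with the largest and 12 with the smallest log2 ratio among the called genes without overlap between groups in the whole library, up to 6 per direction in each class, and the 12 highest and 12 lowest ratios in bulk among genes with a symbol and at least 100 counts in 1 library. It also took the 4 members of each list with the highest mean CPM and every member that was called. Genes outside the rule are named as such.

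Alternatives tried were cell filters of 300 and 1000 genes, at most 10% mitochondrial counts, removal of Scrublet doublets, resolutions of 0.4 and 1.5, clustering without the VEGF and tip cell lists, cells with at least 3 list genes in place of clusters with and without thinning to 1000 counts, DESeq2 1.42.0, median-ratio factors, no filter on low counts, all deposited barcodes, leaving out each library in turn, and other scalings and added CPM for bulk. Leaving out 1 library leaves 1 library in a group, which is then assumed to vary like the other group. Merging barcodes that share 11 of 12 bases, clustering again after thinning each cell to 1000 counts, and list genes in place of clusters for classes other than endothelial were chosen after the data had been seen. Scrublet called only 5 of 10746 cells doublets, so its removal tests nothing. The tests were run on simulated counts drawn at the mean levels of these libraries, with 200 genes changed between the groups. The spread was the fitted trend over expression, with no further spread from gene to gene, so false calls may be understated. In the whole library 40% of 2-fold and 97% of 4-fold changes were recovered with 7 false calls. Within classes 13% to 42% of 2-fold and 65% to 89% of 4-fold changes were recovered, with 2 to 9 false calls, the most in distal nephron-like cells. A bulk list of 20 genes raised 2-fold reached percentile 100, and one left alone percentile 84.4. Plots used matplotlib 3.10.9, with Python 3.11.15, R 4.3.3 and scipy 1.17.1, and random seeds were fixed. No deposited sample was left out.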

Results

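Single-cell gene counts were collected by Drop-seq from day 21 kidney organoids of the H9 embryonic stem cell line, 2 libraries with VEGF165 and 2 without, and bulk RNA counts from 1 library of each kind. The kept cells held 5835319 and 6887159 counts with VEGF and 6351211 and 6965461 without. The median counts per cell were 1602 and 1625 with VEGF and 1494 and 1543 without. The median mitochondrial share was 5.45% and 7.21% with VEGF and 5.05% and 5.14% without. The bulk libraries held 41660275 gene counts with VEGF and 57645470 without. Of the kept barcodes, 40.4% and 30.3% with VEGF and 27.5% and 13% without shared 11 of 12 bases with another barcode of their library. Of the 793 groups of such barcodes, 84.7% fell in 1 cluster, against 1.18% for random groups, so 1 bead was often counted as several cells. Merging them left 1625 and 2225 cells with VEGF and 2179 and 2694 without.

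The labels say that VEGF165 was added to modulate endothelial cells, and the first comparison asked whether their share of cells differed. Cluster 17 was endothelial-like, with 20 of the 24 endothelial markers, and was led by ESM1, a tip cell gene, the surface protein CD34, the junction protein PECAM1 and the VEGF receptor KDR. It held 12 of 2217 and 8 of 2842 cells with VEGF, and 5 of 2710 and 6 of 2977 without. The shares were 0.541% (95% interval 0.280% to 0.944%) and 0.281% (0.122% to 0.554%) with VEGF, and 0.185% (0.0599% to 0.430%) and 0.202% (0.0740% to 0.438%) without. The mean share was 0.411% ± 0.184 with VEGF and 0.193% ± 0.012 without (SD, n = 2 each), a difference of 0.218 percentage points or 2.13-fold. With barcodes that share 11 bases merged, a setting chosen after the data were seen, the shares were 0.572% and 0.226%, a difference of 0.345 points or 2.53-fold (exact permutation p = 0.333). The unmerged difference was 0.0885 points without VEGF replicate 1 and 0.348 without VEGF replicate 2. Both libraries with VEGF lay above both without, but the exact permutation p was 0.333, the smallest this design allows. In the edgeR test over classes the log2 ratio was 1.04 ± 0.48 (SE), adjusted p = 0.153. Cells with counts of at least 3 endothelial list genes, taken without clusters, were 1.45% ± 0.504 with VEGF and 0.725% ± 0.123 without (exact permutation p = 0.333). An edgeR test of them over 15 cell types, chosen after the data were seen, passed (log2 ratio 0.97 ± 0.38, adjusted p = 0.0463, higher in 2 of 2 libraries). In that count the list's CLDN5 was also a leading gene of podocyte-like cluster 3. Free RNA was not taken off. With each cell thinned to 1000 counts the shares were 0.406% and 0.266% and the groups overlapped (exact permutation p = 0.667). The pooled ratio of shares, 2.04, had a counting interval of 0.934 to 4.72. Whether the difference passed therefore depended on how endothelial cells were counted and on the test. The exact permutation test could not pass under any count.

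**Figure D1:**
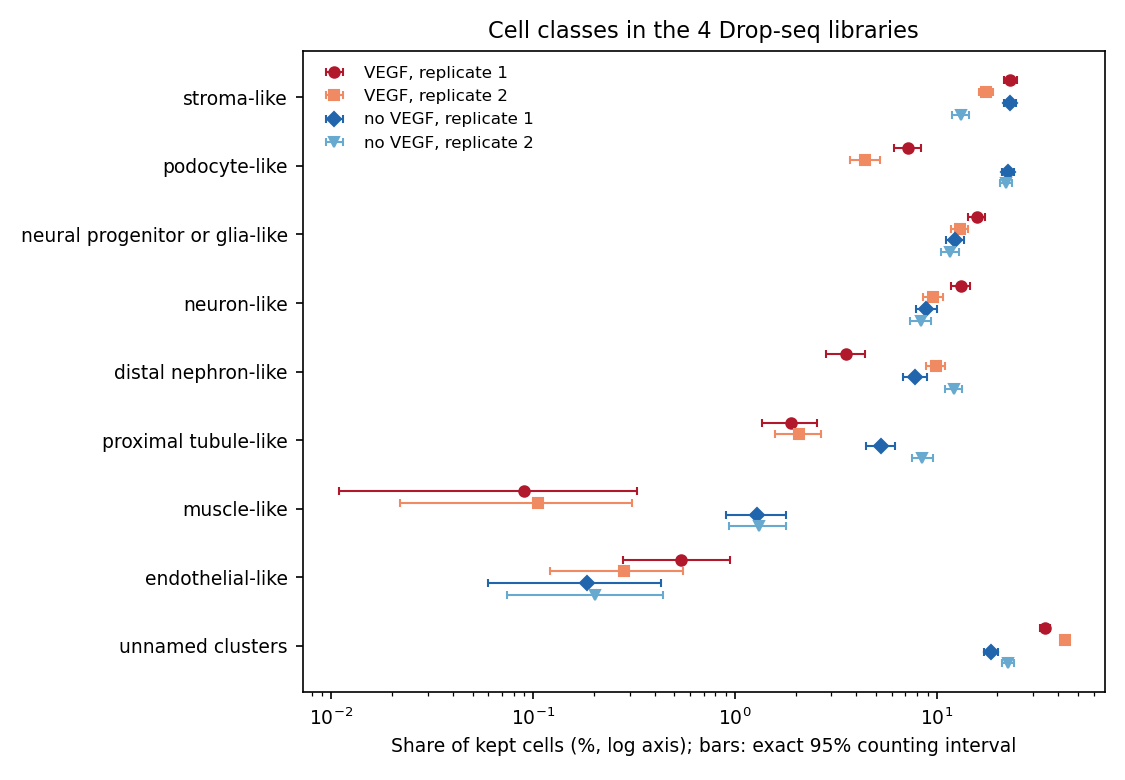
Share of kept cells in percent (log axis) for each class and library, with exact 95% counting intervals. The podocyte-like share lies between 4.43% and 7.22% with VEGF and between 22.1% and 22.5% without, and the endothelial-like intervals overlap.

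The other classes were compared next. Podocyte-like cells, marked by the slit diaphragm genes NPHS1 and NPHS2 and by PODXL, took 5.83% ± 1.97 of cells with VEGF and 22.3% ± 0.313 without, a log2 ratio of -1.94 ± 0.32 (edgeR, adjusted p = 0.00762). Proximal tubule-like cells (LRP2, CUBN and SLC34A1) took 1.99% ± 0.128 against 6.89% ± 2.28, a log2 ratio of -1.79 ± 0.33 (adjusted p = 0.00872). Muscle-like cells (MYOG, MYOD1 and MYLPF) took 0.0979% ± 0.0109, 2 and 3 cells, against 1.30% ± 0.0131, 35 and 39 cells, a log2 ratio of -3.66 ± 0.36 (adjusted p = 0.00148). Unnamed clusters took 38.8% ± 6.03 against 20.6% ± 2.78 (log2 ratio 0.91 ± 0.25, adjusted p = 0.0354). All of these differences had the same direction in 2 of 2 libraries against both others. Shares are parts of a whole, so a lower share can also come from more cells of other classes. The other classes did not pass: distal nephron-like cells were 6.73% ± 4.47 against 9.97% ± 3.04 (adjusted p = 0.387), neural progenitor or glia-like 14.4% ± 1.96 against 12.0% ± 0.423 (adjusted p = 0.387), neuron-like 11.4% ± 2.58 against 8.61% ± 0.398 (adjusted p = 0.283) and stroma-like 20.4% ± 3.95 against 18.1% ± 6.99 (adjusted p = 0.647). At resolution 0.4, where clusters joined, the podocyte-like log2 ratio was -0.52 and the proximal tubule-like one 0.37, and neither was called. The muscle-like call was lost at 300 genes per barcode (log2 ratio -0.69) and with merged barcodes (-0.63), and the proximal tubule-like call without VEGF replicate 1 (adjusted p = 0.119), VEGF replicate 2 (0.0671) or no VEGF replicate 2 (0.0881).

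Within the classes and the unnamed cells, single clusters differed more. Shares of single clusters were not tested with merged barcodes. Cluster 7, unnamed because it held 9 stroma and 5 mural markers but more mural (ACTA2 and TAGLN) than stroma markers (MGP) among its leading genes, was led by ACTA2, a smooth muscle actin, INHBA, an activin subunit, and MGP, a matrix protein. It took 4.47% ± 1.54 of cells with VEGF, which the stroma-like share leaves out. Without VEGF it held 0 of 2710 and 2 of 2977 cells, a ratio of 131 (95% counting interval 35.9 to 1088, edgeR adjusted p = 0.00759). Cluster 4, led by the tight junction gene CLDN1 and CTSC and with the nephron progenitor markers PAX2, PAX8 and LYPD1, took 11.5% ± 1.89 against 1.80% ± 0.691 (adjusted p = 0.0122). Cluster 1, led by MMP7, a matrix metalloprotease, and CLDN6, took 3.83% and 14.1% against 0.738% and 1.24% (adjusted p = 0.0297). Cluster 18, led by NPY and SPRR2F and with STAR, held 0 of 5059 cells with VEGF, which allows a share of up to 0.0593%, and 32 of 2710 (1.18%) and 103 of 2977 (3.46%) without, over the pooled cells at least 40-fold more (adjusted p = 0.0202). Cluster 6, the podocyte-like cluster led by NPHS2, took 0.547% ± 0.375 against 7.20% ± 1.83 (adjusted p = 0.0131), and cluster 3, led by OLFM3, 5.28% ± 1.59 against 15.1% ± 2.15 (adjusted p = 0.0202). Cluster 13, led by the proliferation genes MKI67 and TOP2A, took 2.21% ± 0.0614 against 4.55% ± 1.31 (adjusted p = 0.0487). Different clusters held most of 2 classes in the 2 groups. Of the neuron-like clusters, cluster 15 (CRABP1, MAP2 and VIP) took 8.10% ± 2.39 with VEGF against 1.20% ± 0.552 (adjusted p = 0.0149), while cluster 12 (STMN2, NEUROD1 and ISL1) took 3.30% ± 0.185 against 7.42% ± 0.154 (adjusted p = 0.0173). For short, the neural progenitor or glia-like class is called glia-like from here on, which does not mean that all its cells were glia. Of its clusters, cluster 11 (SCG2, THSD4 and SOX2) took 8.25% ± 0.771 against 1.89% ± 0.15 (adjusted p = 0.00759), while cluster 14 (PLP1 and S100B, Schwann cell genes) took 6.15% ± 1.19 against 10.1% ± 0.273 (adjusted p = 0.0777).

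**Figure D2:**
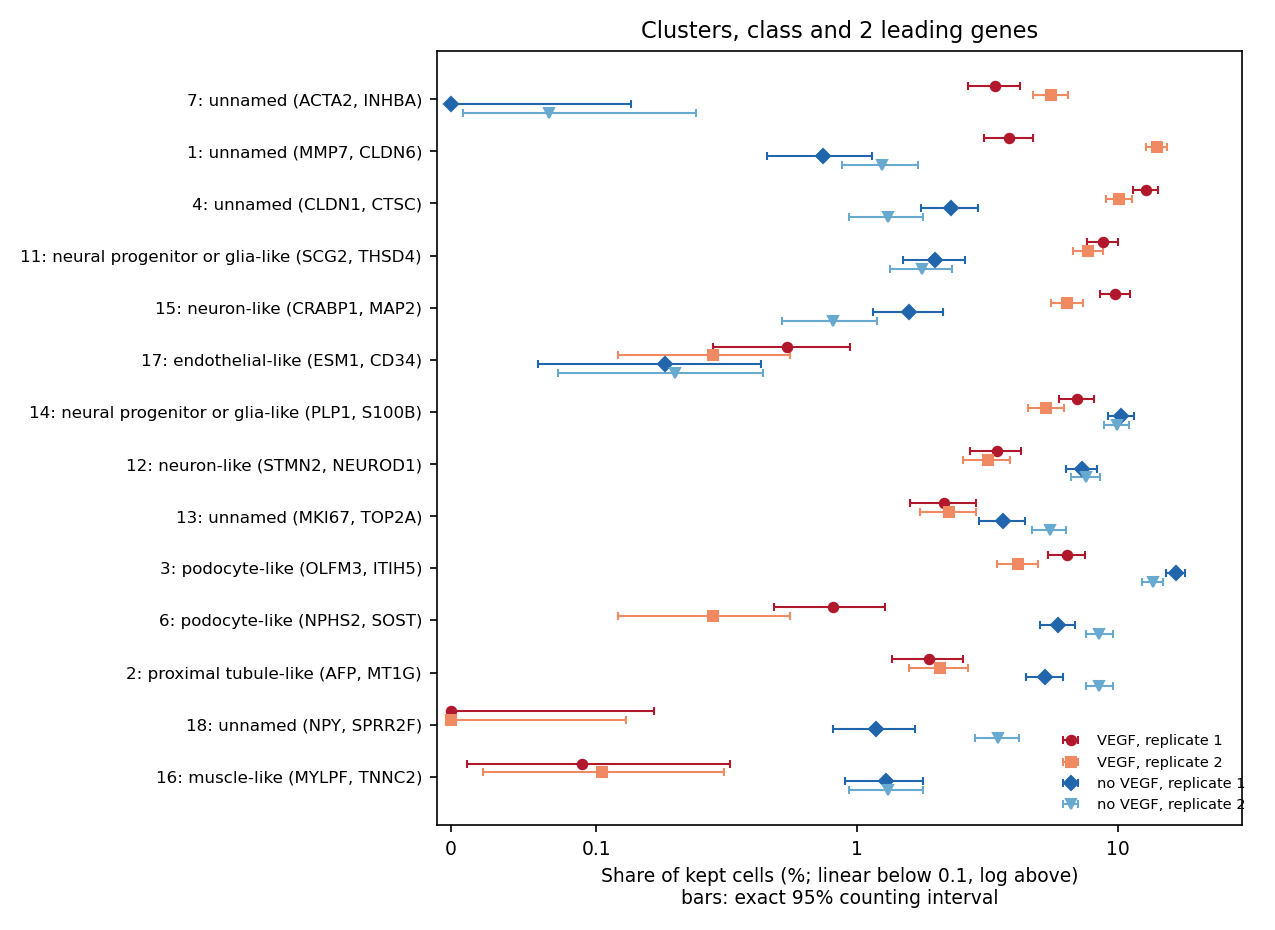
Share of kept cells in percent (linear below 0.1, log above) for clusters of the text, by library, with exact 95% counting intervals. Clusters 7, 1, 4, 11 and 15 are higher in both VEGF libraries than in both others, and clusters 6, 3, 2, 12, 16 and 18 are lower.

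The third comparison asked which genes differed in the sum over all kept cells. Of 16609 genes tested, 627 were higher with VEGF and 382 lower (edgeR, adjusted p under 0.05), and 3217 had an unadjusted p under 0.05. In all 1009 called genes the groups did not overlap. Of all tested genes 49.9% did not overlap, where chance gives 33.3%. The called genes with the largest rises included VIP, a neuropeptide, at 14.5 ± 1.73 CPM against 0.304 ± 0.0121 (log2 ratio 5.49 ± 0.46, adjusted p = 4.15e-05), NNMT, a methyltransferase, at 28.9 ± 9.27 against 0.837 ± 0.141 (5.08 ± 0.40), and SERPINE1, the plasminogen activator inhibitor, at 28.1 ± 0.951 against 0.890 ± 1.04 (4.93 ± 0.47). Elastin (ELN) was 108-fold higher (95% counting interval 19.0 to 4308), C1orf61 107-fold (36.3 to 522), CDKN2B, a cyclin-dependent kinase inhibitor, 65.5-fold (11.3 to 2626), the homeobox gene LHX2 39.5-fold (10.6 to 332), the chemokine gene CXCL5 35.3-fold (9.41 to 298) and OR8S1 34.3-fold (5.74 to 1395). RP11-865I6.2 was at least 24.6-fold higher, CCL3, a chemokine gene, at least 22.1-fold, and PRDM14, a pluripotency regulator, at least 8.73-fold. CCL3 was uneven, at 2.81 and 7.24 CPM with VEGF (fitted log2 ratio 7.18 to 8.58 with 1 library left out). The largest falls were in SPRR2F, at least 42.2-fold lower, but with 3.59 and 16.4 CPM without VEGF (fitted log2 ratio -9.75 to -7.52 with 1 library left out), GLYAT and APOB, genes of liver and tubule metabolism, at least 11.6-fold and 11.5-fold lower, and HFE2, at least 8.95-fold lower. The muscle genes TRDN (86.6-fold, 15.2 to 3459), MYBPC1 (33.7-fold, 5.66 to 1368), LRTM1 (38.0-fold, 10.2 to 319), LMOD3 (24.5-fold, 6.46 to 208) and MYBPH (13.8 ± 6.34 CPM without VEGF against 0.309 ± 0.203 with) were lower. So were SCML4 (53.9-fold, 9.29 to 2167), AGXT2 (40.4-fold, 6.87 to 1634) and RP11-535A5.1 (32.7-fold, 5.49 to 1330). Without no VEGF replicate 2 the counts were 341 higher and 204 lower, without VEGF replicate 2 they were 1102 and 758, and without VEGF replicate 1 608 were lower.

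The podocyte and tubule lists fell, and the nephron progenitor list did not. Of 14 podocyte genes tested 12 fell and 0 rose (14 fell when adjusted over the list alone). NPHS2 fell from 314 ± 149 to 56.1 ± 13.2 CPM (log2 ratio -2.48 ± 0.29, adjusted p = 0.000438), PODXL from 364 ± 17.7 to 98.8 ± 42.5 (-1.88 ± 0.25), MAFB, a podocyte transcription factor, from 651 ± 142 to 230 ± 37.5 (-1.50 ± 0.20) and DDN from 9.24 ± 0.706 to 0.970 ± 0.733 (-3.25 ± 0.48). The list's median log2 ratio was -1.39 (camera, adjusted p = 4.23e-26; adjusted p = 0.147 with an estimated correlation). Of 9 proximal tubule genes 5 fell (8 when adjusted over the list alone; median -1.18, camera adjusted p = 8.40e-11; adjusted p = 0.147 with an estimated correlation). Among them were the phosphate transporter SLC34A1 (20.9 ± 2.01 to 2.42 ± 0.846 CPM) and the transcription factor HNF4A (4.88 ± 2.49 to 0.557 ± 0.148). Of 12 distal nephron genes 4 fell (7 fell and 1 rose when adjusted over the list alone), with SLC12A1, the thick limb transporter, at 1.95 ± 0.653 against 10.2 ± 6.03 CPM and CALB1 at 0.550 ± 0.0756 against 7.28 ± 7.86 (median -0.65, camera adjusted p = 5.63e-05; adjusted p = 0.375 with an estimated correlation). Of 12 nephron progenitor genes 0 passed (0 when adjusted over the list alone), with a median of -0.02 and a mean of 0.08 (camera adjusted p = 0.853).

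Vessel lists moved less evenly. Of 12 endothelial genes tested 2 rose: the VEGF receptor FLT1, from 1.96 ± 0.781 to 15.9 ± 4.31 CPM (log2 ratio 3.01 ± 0.38, adjusted p = 0.000635), and the transcription factor ERG, from 0.595 ± 0.62 to 6.22 ± 2.72 (3.33 ± 0.62). Adjusted over the list alone 3 rose and 1 fell. CLDN5 was 35.3 ± 19.6 against 74.8 ± 11.7 CPM (adjusted p = 0.0533) and EGFL7 54.3 ± 12.1 against 33.3 ± 1.22 (adjusted p = 0.075). The list's median was 0.30 (camera adjusted p = 0.0132; adjusted p = 0.19 with an estimated correlation), and without VEGF replicate 1 the camera adjusted p was 0.0703. Of 13 tip cell and VEGF-Notch genes, ESM1 (0.529 ± 0.0863 to 7.93 ± 3.75 CPM), RND1 and IGFBP3 rose and KCNE3 fell (8 rose and 2 fell when adjusted over the list alone). The median was 1.05 (camera adjusted p = 0.00294; adjusted p = 0.19 with an estimated correlation; 0.0757 without VEGF replicate 1). Of 9 VEGF ligand and receptor genes, 1 rose (FLT1) and 1 fell, the lymphatic ligand VEGFD, at 0.550 ± 0.0756 against 5.75 ± 0.844 CPM (the same numbers when adjusted over the list alone). VEGFA was 78.7 ± 41.2 against 96.3 ± 2.18 CPM (adjusted p = 0.622), and the list's median was -0.29 (camera adjusted p = 0.642). Mural genes, of pericytes and smooth muscle, rose in 5 of 10 (8 when adjusted over the list alone): ACTA2 from 56.1 ± 13.8 to 407 ± 171 CPM (2.86 ± 0.28), TAGLN from 94.1 ± 0.872 to 502 ± 67.7 (2.41 ± 0.18), NOTCH3, RGS5 and MYH11 (median 1.54, camera adjusted p = 6.25e-13; adjusted p = 0.147 with an estimated correlation).

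Stroma genes rose in 6 of 14 (8 when adjusted over the list alone), with MGP, an inhibitor of calcification, from 12.3 ± 2.21 to 310 ± 111 CPM (log2 ratio 4.65 ± 0.28, adjusted p = 3.5e-06), LUM from 2.13 ± 0.0845 to 21.3 ± 2.96 and COL1A1 from 74.4 ± 22.4 to 226 ± 13 (median 0.83, camera adjusted p = 7.60e-13; adjusted p = 0.161 with an estimated correlation). COL1A2, at 690 ± 42.4 against 661 ± 64.8 CPM, and POSTN did not pass. Cartilage genes rose in 4 of 7 (5 when adjusted over the list alone; median 1.21, camera adjusted p = 9.14e-08; adjusted p = 0.147 with an estimated correlation), among them COL2A1, COL11A1 and SOX9. Glomerular basement membrane genes rose in 2 of 11, COL4A1 from 107 ± 15.7 to 288 ± 46.4 CPM and COL4A2 from 146 ± 15 to 272 ± 24.7 (2 when adjusted over the list alone). Both are chains of basement membranes in general. The list was not called in the main setting (median 0.13, camera adjusted p = 0.0696), but it was with all deposited barcodes (camera adjusted p = 0.0469). Pluripotency genes rose in 4 of 7 (6 when adjusted over the list alone), with POU5F1 from 0.308 ± 0.227 to 4.42 ± 2.41 CPM and L1TD1 from 6.03 ± 1.63 to 27.7 ± 10.8 (median 1.35, camera adjusted p = 6.69e-06; adjusted p = 0.248 with an estimated correlation).

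Neural lists were mixed. Of 10 neural progenitor or glia genes 4 rose, among them SOX2, a neural progenitor factor, from 12.8 ± 1.58 to 43.0 ± 1.65 CPM, and 1 fell, PLP1, a myelin gene, from 181 ± 8.92 to 81.8 ± 18.5 (5 and 1 when adjusted over the list alone; median 0.42, camera adjusted p = 0.0113; adjusted p = 0.19 with an estimated correlation). Of 11 neuron genes GAP43 rose and NEUROD1 and ISL1 fell (2 and 3 when adjusted over the list alone; median -0.14, camera adjusted p = 0.127). The neuron list was called without VEGF replicate 1 (0.0158) and without no VEGF replicate 2 (0.0485). Muscle genes fell in 6 of 9 (8 when adjusted over the list alone), with MYLPF, a myosin light chain, from 159 ± 8.77 to 13.1 ± 0.814 CPM (median -1.89, camera adjusted p = 8.51e-20; adjusted p = 0.147 with an estimated correlation). Melanocyte genes fell in 2 of 4 (3 when adjusted over the list alone), PMEL and DCT (median -1.22, camera adjusted p = 7.71e-06; adjusted p = 0.147 with an estimated correlation). Endoderm genes fell in 3 of 3 (3 when adjusted over the list alone), AFP, APOA1 and FGB (median -3.00, camera adjusted p = 8.99e-12; adjusted p = 0.147 with an estimated correlation); AFP was also the leading gene of proximal tubule-like cluster 2. Of 2 blood genes AIF1 fell (1 when adjusted over the list alone; median -1.48, camera adjusted p = 0.000842; adjusted p = 0.19 with an estimated correlation).

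Genes that respond to cell dissociation, the immediate early list, rose in 7 of 14 (9 when adjusted over the list alone). JUNB rose from 7.31 ± 1.58 to 43.8 ± 27 CPM, FOS from 5.61 ± 3.76 to 25.2 ± 4.65 and IER3 from 19.4 ± 5.49 to 85.5 ± 4.47 (median 1.52, camera adjusted p = 8.32e-11; adjusted p = 0.248 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.37 with 0 of 14 called (0 when adjusted over the list alone; camera adjusted p = 0.0142; adjusted p = 0.603 with an estimated correlation), and the call was lost without VEGF replicate 1 (0.75) and without no VEGF replicate 2 (0.204). Proliferation genes had a median of -0.25 with 0 of 14 called (0 when adjusted over the list alone; camera adjusted p = 0.00817; adjusted p = 0.19 with an estimated correlation). Mitochondrially encoded genes had a median of -0.02 with 0 of 13 called (camera adjusted p = 0.640), although the list was called without VEGF replicate 2 (0.0313).

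The fourth comparison asked which genes differed within a class. Counts of genes higher and lower with VEGF were 369 and 275 of 8159 in glia-like cells, 257 and 248 of 7009 in neuron-like cells, 248 and 116 of 10025 in stroma-like cells, 119 and 65 of 9816 in podocyte-like cells, 35 and 10 of 7655 in proximal tubule-like cells and 16 and 3 of 8305 in distal nephron-like cells (edgeR). DESeq2 called fewer: 130 and 121, 81 and 69, 101 and 41, 47 and 28, 13 and 2, and 8 and 0. In neuron-like and glia-like cells the groups were drawn mostly from different clusters, so these counts hold differences of subtype. Called within single clusters were 37 and 8 genes in cluster 11, 160 and 98 in cluster 14, 118 and 78 in cluster 12 and 8 and 7 in cluster 15. The podocyte-like class also changed in make-up, and within its cluster 3 they were 46 and 22. In stroma-like clusters 8, 9 and 10 they were 91 and 38, 114 and 64, and 111 and 32. Muscle-like and endothelial-like cells were too few to test. Leaving out 1 library moved many of these counts. Without no VEGF replicate 2 they were 199 and 126 in glia-like, 123 and 98 in neuron-like, 51 and 12 in podocyte-like and 14 and 4 in proximal tubule-like cells, and 77 were lower in stroma-like and 1 in distal nephron-like cells. Without VEGF replicate 2 they were 326 and 252 in podocyte-like, 106 and 49 in proximal tubule-like and 71 and 44 in distal nephron-like cells. Without VEGF replicate 1 they were 153 and 157 in neuron-like, 14 and 2 in proximal tubule-like and 89 and 38 in distal nephron-like cells. Without no VEGF replicate 1, 29 were higher and 10 lower in distal nephron-like cells, 160 lower in neuron-like and 113 lower in podocyte-like cells.

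In podocyte-like cells 5 of 14 podocyte genes fell with VEGF and 0 rose (12 fell when adjusted over the list alone; median log2 ratio -0.63; camera adjusted p = 1.56e-10; adjusted p = 0.379 with an estimated correlation). NPHS2 was 545 ± 307 against 1256 ± 481 CPM (log2 ratio -1.23 ± 0.30, adjusted p = 0.0431), THSD7A 40 ± 13.5 against 224 ± 105 (-2.44 ± 0.36), and MAFB, TCF21 and DDN fell too. These markers helped to name the class, and cluster 6, which held more of them than cluster 3, made up less of the class with VEGF. The largest rises were in PMEPA1, a TGF-beta target, at 67.6 ± 44.6 against 4.39 ± 0.22 CPM (3.99 ± 0.49, adjusted p = 0.000478), TNFRSF12A, the TWEAK receptor, at 221 ± 24.5 against 19.2 ± 4.95 (3.52 ± 0.29, adjusted p = 6.92e-06), MAFF, PHLDA2, TINAGL1 and the immediate early gene JUNB. FAM111B was at least 4.16-fold lower. The cell cycle gene CDCA7, 10.2-fold lower (2.71 to 85.7), and the kinetochore gene ZWINT, 10.3-fold lower (2.75 to 87.0), fell with LRRIQ1, CAPN8 and TDRD5. The hypoxia and glycolysis list rose with 3 of 11 called (camera adjusted p = 4.95e-07; adjusted p = 0.462 with an estimated correlation), among them the glucose transporter SLC2A1 at 535 ± 447 against 110 ± 79.3 CPM. The immediate early list rose with 5 of 12 called (camera adjusted p = 5.64e-08; adjusted p = 0.379 with an estimated correlation).

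LEFTY1, an inhibitor of Nodal signalling, rose in tubule-like cells, and also in podocyte-like cells (log2 ratio 2.34 ± 0.28) and in unnamed clusters 0 (4.68 ± 0.50) and 13 (4.13 ± 0.54). It did not pass in unnamed clusters 1 (-0.31 ± 0.61, adjusted p = 0.971) and 4 (3.34 ± 0.71, adjusted p = 0.0988). It was 202 ± 47.7 against 13.7 ± 4.43 CPM in proximal tubule-like cells (log2 ratio 3.84 ± 0.37, adjusted p = 6.13e-05) and 98.8 ± 23.9 against 14.4 ± 4.98 in distal nephron-like cells (2.75 ± 0.39, adjusted p = 0.00726). LEFTY2, LMO2, KIT and EGR1 rose in proximal tubule-like cells. The metallothioneins MT1G, at 81.5 ± 92 against 495 ± 221 CPM, and MT1H fell there, as did APOA1, B9D1 and PODXL, and SCML4 was at least 5.84-fold lower. The distal nephron-like cells held 3 falling genes: NPNT, at 3.56 ± 5.04 against 57.9 ± 3.84 CPM, SLC12A1, at 6.32 ± 1.14 against 57.0 ± 25.7, and GMNN, a replication regulator. MGP, PVRL3-AS1, ACTA2, ITGB6 and PTRF rose there. The mural list, which holds ACTA2, was shifted up in every class: distal nephron-like (2 of 3 genes rose, 2 when adjusted over the list alone; camera adjusted p = 1.09e-09), proximal tubule-like (2 of 4, 4; 9.60e-09), stroma-like (3 of 7, 5; 1.93e-09), glia-like (2 of 5, 4 and 1 fell; 3.86e-06), podocyte-like (2 of 6, 4; 0.000117) and neuron-like cells (2 of 3, 2; 0.00577). None held with an estimated correlation (adjusted p = 0.379, and 0.451 in neuron-like cells). Free RNA from cluster 7, which ACTA2 led, was not excluded.

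In glia-like cells 4 of 5 pluripotency genes tested rose (4 when adjusted over the list alone; camera adjusted p = 9.69e-07; adjusted p = 0.384 with an estimated correlation). With VEGF 195 of 350 and 219 of 370 cells of this class were in cluster 11, marked by SOX2. Within that cluster L1TD1 (295 CPM with VEGF against 0) and LIN28A (118 against 5.21) were called. Of 10 neural progenitor or glia genes, which named the class, 4 rose and 2 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.0828). THSD4 was 246-fold higher (43.8 to 9765), C1orf61 at least 38.5-fold, POU5F1 at least 12.8-fold and PRDM14 at least 7.25-fold, L1TD1 rose from 27.1 ± 0.174 to 172 ± 102 CPM, and SOX2 from 89.0 ± 4.85 to 232 ± 18.1. PLP1 fell from 1845 ± 110 to 686 ± 140 CPM, and ABCC2, KCNK5, TGFBR3, TCERG1L, FAM78B and FLJ12825 had the largest falls. In neuron-like cells the rising genes included LINC00461 (at least 32.6-fold), C1orf61 (at least 28.8-fold), ELN (at least 13.4-fold), LHX2 (at least 12.8-fold), MIR9-3HG (at least 9.12-fold) and VIP, at 197 ± 52.5 against 5.25 ± 0.0706 CPM (5.14 ± 0.46, adjusted p = 2.06e-09). VIP marks cluster 15, and within that cluster its log2 ratio was 2.75 ± 0.58, at 367 against 57.9 CPM (adjusted p = 0.00956). The homeobox genes TLX2, 20.8-fold lower (6.74 to 104), HMX1, at 6.87 ± 3.93 against 87.9 ± 19.3 CPM, and ISL1, at 198 ± 43.3 against 404 ± 96.5, fell. ITIH5, at least 9.89-fold lower, SLC51B, MRVI1 and BRINP2 fell too. In stroma-like cells NNMT, RUNX1, LEFTY2, LINC00461, RP11-865I6.2 and C1orf61 had the largest rises, and COL4A1 rose from 110 ± 14.6 to 358 ± 22.6 CPM (1.69 ± 0.21). The muscle genes MYL1 (at least 39.4-fold), TNNC2 (log2 ratio -4.75 ± 0.43), MYLPF and MSTN, VEGFD (at least 9.97-fold) and DPF3 fell there. Of 7 muscle list genes 3 fell in stroma-like cells (5 when adjusted over the list alone; camera adjusted p = 3.46e-11; adjusted p = 0.379 with an estimated correlation). Muscle-like cells were 5 with VEGF and 74 without, and free RNA from them was not excluded.

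Some genes moved across classes. Of the called genes 19 were higher in at least 4 of the 6 classes and 1 lower. In exactly 3 classes 22 were higher and 26 lower. Of the 27 genes lower in at least 3 classes 11 were ribosomal protein genes. The median share of ribosomal protein genes in a cell's counts was 14.4% and 14.6% with VEGF and 16.7% and 15.7% without. FST, an activin antagonist, was called in 4 classes, with log2 ratios of 5.10 ± 0.34 in glia-like, 4.28 ± 0.47 in neuron-like, 2.67 ± 0.53 in proximal tubule-like and 1.94 ± 0.20 in stroma-like cells. It falls outside the rule for named genes and was chosen after its values were seen. MGP was called in all 6. Its level was 849 ± 180 CPM with VEGF in stroma-like cells and 34.1 ± 11 to 61 ± 38.3 in the other 5 classes, where free RNA from other cells was not excluded. PODXL was lower in neuron-like (10.4 ± 11.3 against 79.1 ± 45.6 CPM), stroma-like (7.22 ± 1.64 against 48.8 ± 6.54) and proximal tubule-like cells, against 870 ± 176 and 1389 ± 74.3 in podocyte-like cells (adjusted p = 0.0537). Of the podocyte list 9 of 10 genes fell in neuron-like cells (9 when adjusted over the list alone; camera adjusted p = 2.29e-10) and 7 of 12 in stroma-like cells (8; 5.67e-13), each with adjusted p = 0.379 with an estimated correlation. Free RNA from podocyte-like cells was not excluded there.

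Program lists were tested in each class, and none held with an estimated correlation (lowest adjusted p = 0.379). The proliferation list was shifted down in glia-like cells (3 of 14 genes fell, 6 when adjusted over the list alone; camera adjusted p = 6.78e-06), neuron-like cells (2 of 8, 5; 0.000143) and podocyte-like cells (1 of 9, 4; 4.47e-05). It was also shifted down, with 0 genes called, in distal nephron-like cells (0 of 9, 0; 0.000464) and proximal tubule-like cells (0 of 8, 1; 0.000464), but not in stroma-like cells (0 of 14, 0; 0.453). The immediate early list was shifted up in glia-like cells (4 of 8 genes rose, 5 when adjusted over the list alone; 0.00195), proximal tubule-like cells (3 of 7, 5; 4.66e-08), stroma-like cells (4 of 12, 6; 0.000481) and, with 0 called, distal nephron-like cells (0 of 9, 0; 0.0161). In neuron-like cells it did not pass (1 of 4, 1; 0.270). The hypoxia and glycolysis list was shifted up in neuron-like cells (3 of 8, 4; 0.00523), glia-like cells (1 of 10, 1; 0.0111) and, with 0 called, distal nephron-like (0 of 10, 1; 0.0103), proximal tubule-like (0 of 10, 0; 0.0329) and stroma-like cells (0 of 10, 2; 0.0172). In stroma-like cells the basement membrane list was shifted up (2 of 8, 3; 0.00399) and the VEGF list down (1 of 7, 1; 0.0264). In proximal tubule-like cells the basement membrane list was shifted up (0 of 8, 0; 0.0400) and the mitochondrially encoded list down (0 of 13, 0; 0.0240). In neuron-like cells only 2 tip cell genes were tested and 1 fell (1 when adjusted over the list alone; 0.0115).

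**Figure D3:**
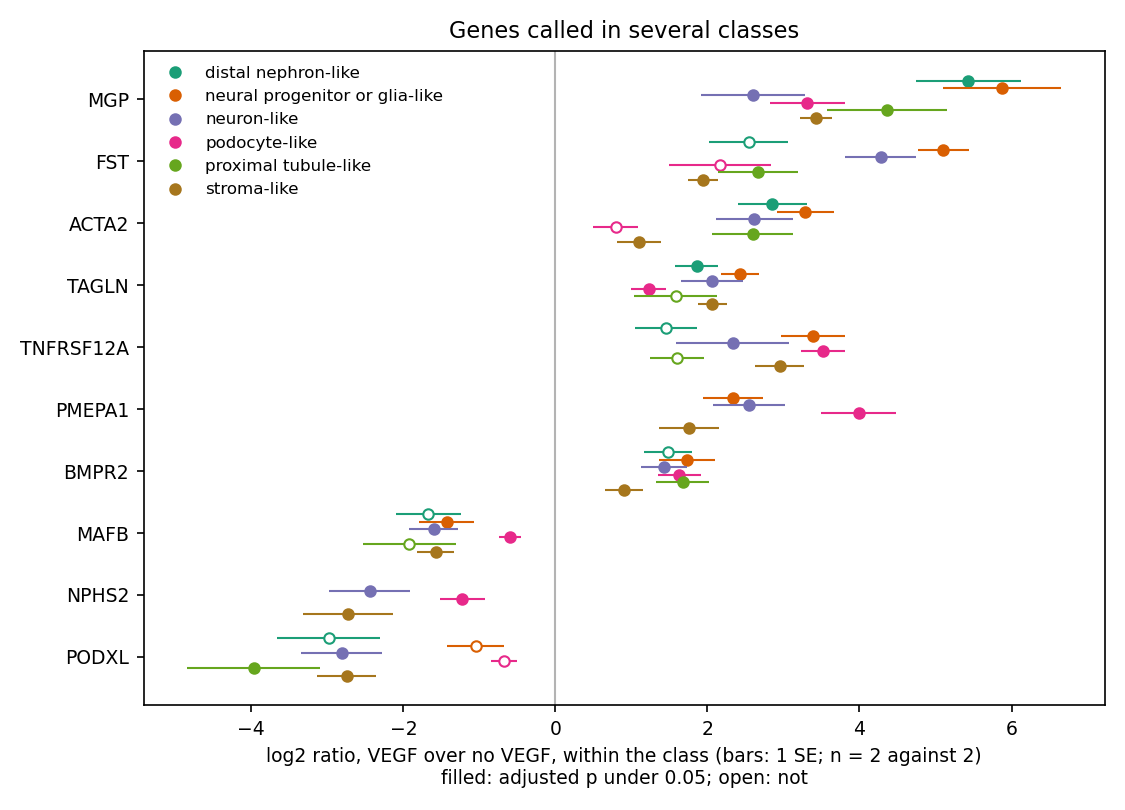
Log2 ratio (VEGF over no VEGF, bars 1 SE, n = 2 against 2) of 10 genes in each class, filled where called. MGP was called in all 6 classes, and PODXL, MAFB and NPHS2 had negative ratios in every class where they were tested.

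Bulk values came from 1 library per group, so no spread between replicates is known. The endothelial list had the third largest median shift of the 22 lists. Of its 24 genes 21 were at least 2-fold higher with VEGF and 0 at least 2-fold lower, with a median log2 ratio of 2.10 (counting interval 2.01 to 2.18), at percentile 100 of random lists. PECAM1 was 258 against 34.0 CPM (log2 ratio 2.89, counting interval 2.82 to 2.96), and KDR 185 against 58.1 (1.65). CDH5 (VE-cadherin), 126 against 19.7 CPM (2.62), and CLDN5, 73.2 against 98.1 (-0.42), fall outside the rule for named genes and were chosen after their values were seen. Tip cell and VEGF-Notch genes were at least 2-fold higher in 9 of 16 (median 1.13, percentile 100), with ESM1 at 241 against 15.9 CPM (3.84). Among VEGF ligands and receptors 3 of 10 were at least 2-fold higher and 2 lower (median 0.35, percentile 98.3). FLT1 was 273 against 21.7 CPM (3.60, 3.52 to 3.68) and VEGFA, the gene of the added factor, 69.3 against 197 (-1.50, -1.56 to -1.44). NRP1 and NRP2 were 0.09 and 0.10, and their sign turned with total counts only (-0.05 and -0.04).

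The 12 highest ratios also held the pluripotency genes PRDM14 (4.35, 4.23 to 4.37), POU5F1 (3.88), TDGF1 (3.79) and L1TD1 (3.70). They held OTX2 (4.10, 3.99 to 4.13), a forebrain factor, SERPINE1 (3.73), GPR183 (3.77), ADGRL4 (3.61), an endothelial receptor, and FIBIN (3.60). ESRG, also among them, was at least 560-fold higher, a bound with no CPM added. The 1 CPM added elsewhere limits a ratio and its interval where a group was near 0 CPM. PRDM14 had 780 counts with VEGF against 1 and OTX2 654 against 1, so their ratios understate the fold. The ratio of MYH8 below does so too. The 12 lowest held the muscle genes MYH8 (63.0 CPM without VEGF and 0.353 with, log2 ratio -5.56), MYL1 (-5.18), MYL11 (MYLPF in the Drop-seq data, -4.99), TNNC2 (-4.78), MYBPC1 (-4.76), MYBPH (-4.51), MYH3 (-4.48), TNNT3 (-4.40), ACTN2 (-4.19) and ACTA1 (-3.89), the neuropeptide NPY (-4.02) and the podocyte gene DDN (-3.79). By list, the medians were 2.85 for pluripotent, 1.78 for mural and 0.71 for immediate early genes, each at percentile 100, and -2.63 for muscle, -1.66 for podocyte, -0.73 for proximal tubule and -0.73 for neuron genes, each at percentile 0. Cartilage (0.41, percentile 99.8), stroma (0.35, 99.0), neural progenitor or glia (0.35, 99.2) and proliferation (0.35, 99.1) lay above the 95% range of random lists. Distal nephron (-0.30, 0.83) and nephron progenitor (-0.35, 0.82) lay below it. That range ignores correlation between genes of a list, so lying outside it is not a test. Within it lay melanocyte (-0.07, 32.2), blood (-0.11, 25.5), endoderm (0.20, 97.4; mean -0.03), glomerular basement membrane (0.30, 95), hypoxia and glycolysis (0.01, 26.4) and mitochondrially encoded genes (0.31, 96.5). Of 15826 genes 702 were at least 2-fold higher and 614 lower, 53.3% higher. With total counts only, which shifted the median of all genes by -0.13, the counts were 558 and 837, 40% higher, and with 5 CPM added 422 and 230, 64.7% higher.

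**Figure D4:**
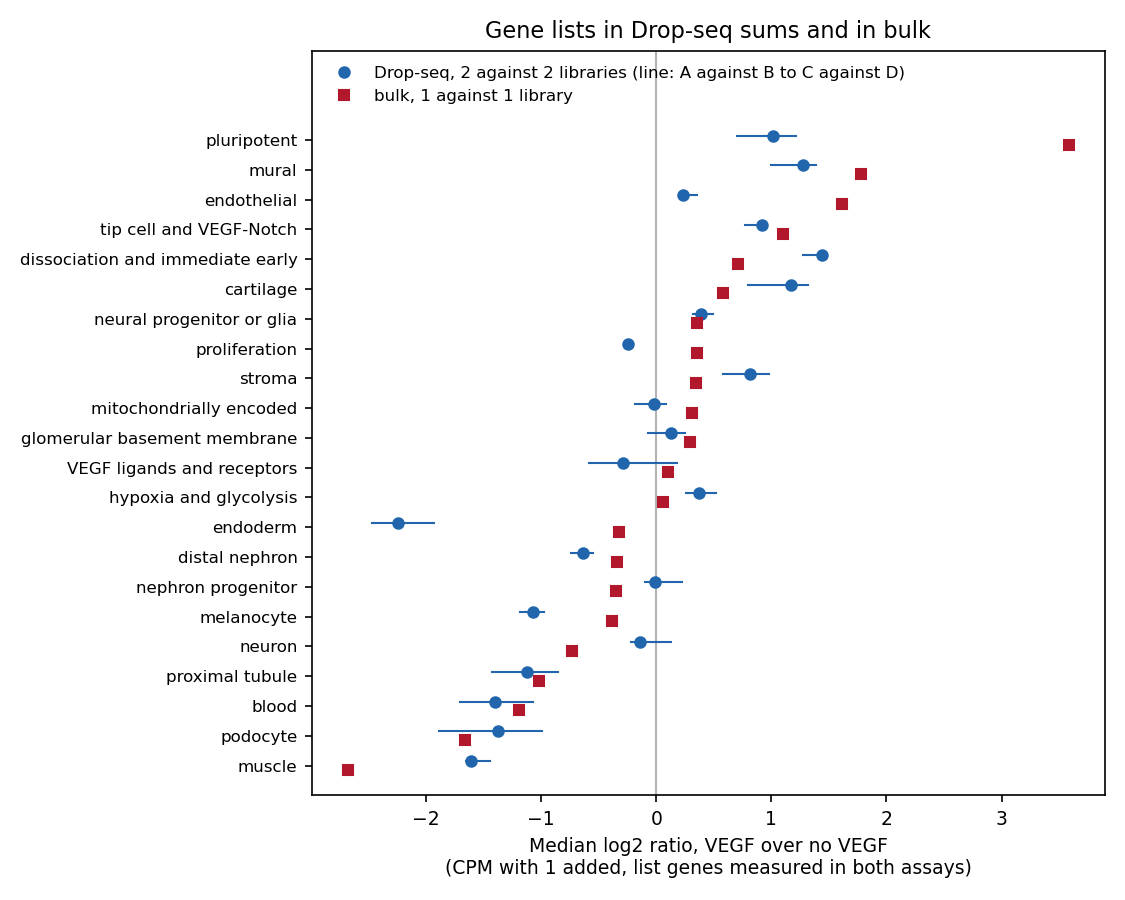
Median log2 ratio (VEGF over no VEGF) of each gene list in the Drop-seq sums and in bulk, over the genes measured in both. The endothelial median is 0.23 in Drop-seq and 1.62 in bulk, and the podocyte median -1.38 and -1.66.

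The last comparison set the assays side by side over 13946 genes. Pearson's r of the log2 ratios was 0.592 and Spearman's rho 0.396, across genes, which are not independent replicates. Of 917 genes called in the Drop-seq sums, 843 (91.9%) had the same sign in bulk, against 61.3% of all genes. Among rising genes these were 509 of 567 and among falling genes 334 of 350. With libraries A and B alone r was 0.507, and with C and D alone 0.579. Over the 12 endothelial genes measured in both, with 1 CPM added, the median was 0.23 in Drop-seq and 1.62 in bulk. Over such genes the medians of proliferation (-0.25 and 0.35), VEGF ligands and receptors (-0.29 and 0.10) and mitochondrially encoded genes (-0.02 and 0.31) had opposite signs. In Drop-seq itself the sign of the last 2 lists turned between library pairs. The VEGF list was 0.18 in A against B and -0.58 in C against D, and the mitochondrially encoded list -0.18 and 0.09. On GRCh38 FLT1 lies on chromosome 13 from 28300344 to 28495145, ESM1 on chromosome 5 from 54977864 to 55022671, MGP on chromosome 12 from 14881181 to 14885926, NPHS2 on chromosome 1 from 179550539 to 179575952 and LEFTY1 on chromosome 1 from 225886282 to 225911382, all protein-coding genes.

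**Figure D5:**
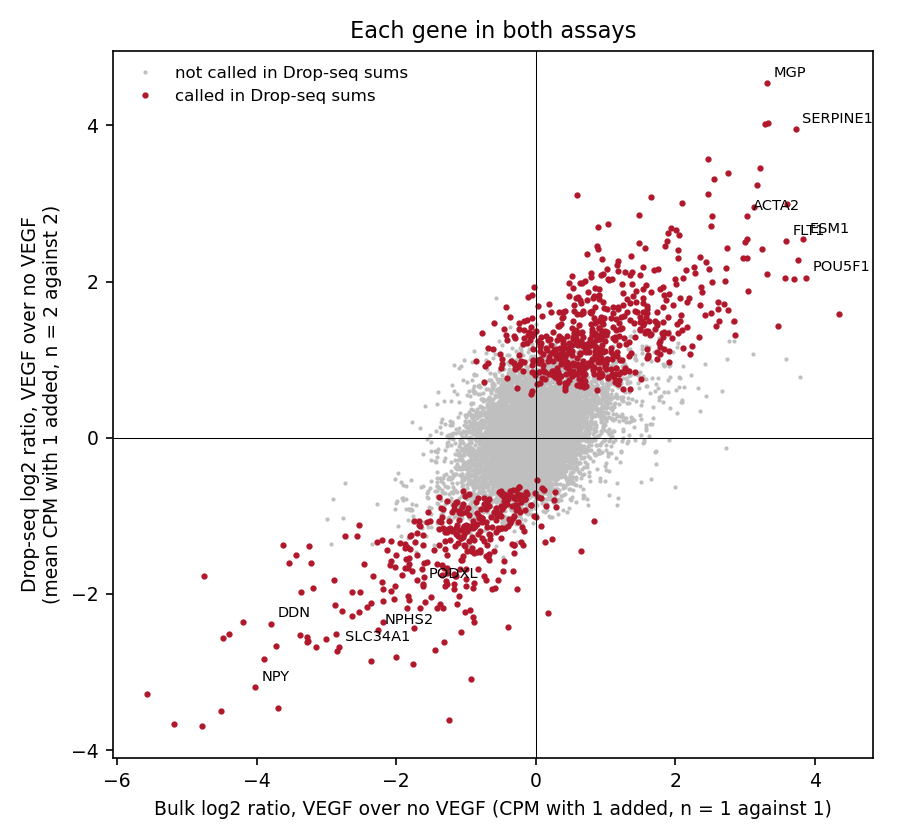
Log2 ratio of each gene (VEGF over no VEGF, CPM with 1 added) in bulk (1 against 1 library) and in the Drop-seq sums (2 against 2), with called genes in red. Of the 917 called genes, 843 have the same sign in both.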

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

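Of the tests in this part, only the MGP test was written before its result was seen; the contrasts between classes and the other tests were chosen after.

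A test of the difference in response to VEGF between each class and the mean of the others called, of 10571 genes with counts in every class and group, 374 in glia-like, 114 in neuron-like, 110 in podocyte-like, 62 in stroma-like, 21 in proximal tubule-like and 16 in distal nephron-like cells. For genes with 0 counts in a group of some class the test mostly could not tell. The genes named for the largest rises and falls of each class made 69 pairs of gene and class. Of these pairs 38 were such, and 28 of those had an unadjusted edgeR p over 0.9. Not passing is therefore no sign of an equal response for them. Of the 28 pairs with counts in every group 4 passed, and of the 38 only ITIH5 in neuron-like cells. In glia-like cells EGLN3, a hypoxia-induced hydroxylase, rose more than in the mean of the other classes (difference of log2 ratios 3.96, adjusted p = 0.0111). It had 49 counts with VEGF and 1 without, a ratio of 47.0 (95% counting interval 8.04 to 1892), and the class held more of cluster 11 with VEGF and mostly cluster 14 without. It was also called within cluster 11, at 70.2 CPM with VEGF and 0 counts without (adjusted p = 0.0208). In neuron-like cells ITIH5 fell more (fitted difference -6.62, adjusted p = 0.0246). That fit is no bound, since ITIH5 had 0 counts there with VEGF and was at least 9.89-fold lower, and it was also a leading gene of podocyte-like cluster 3. LRRIQ1 fell more in podocyte-like cells (-3.43, adjusted p = 0.0468; 13.9-fold lower, 2.36 to 560) and B9D1 in proximal tubule-like cells (-4.27, adjusted p = 0.0160; 19.7-fold lower, 3.40 to 792). The muscle gene TNNC2 fell more in stroma-like cells (-2.91, adjusted p = 0.0217), where 3 of 7 muscle list genes fell. Muscle-like cells were 5 with VEGF and 74 without, and free RNA from them was not tested. Each of these rests on 2 libraries per group.

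Clusters of the same class differed in opposite directions, with both VEGF libraries on 1 side of both others. Glia-like cluster 11 (SOX2) was higher with VEGF, and cluster 14 (PLP1) was lower but did not pass (log2 ratio -0.72, adjusted p = 0.0777), a difference of log2 share ratios of 2.84. Neuron-like cluster 15 (VIP) rose and cluster 12 (NEUROD1) fell, a difference of 3.93. Neither difference was itself tested.

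Free RNA from other cells was weighed for genes that moved across classes. In the VEGF libraries the ratio of MGP to COL3A1 differed between the 5 classes other than stroma-like by 11-fold and 20.8-fold (chi-square p = 2.7e-16). By the test as written this argues against free RNA, but COL3A1 was itself high in podocyte-like cells, at 394 and 331 CPM, so that test assumed too much. The rule that sets it aside was made after the value was seen, and for MGP free RNA stays open. For FST, RNA from stroma-like cells would bring MGP too, so its ratio to MGP was set against the highest in a stroma-like cluster of the same library. It was above that by 4-fold and 4.3-fold in glia-like cells (lower 95% limits 2.59 and 3.23), but 1.74-fold and 5.06-fold in neuron-like cells (0.967 and 3.18) and 2.19-fold and 0.774-fold in proximal tubule-like cells (1.00 and 0.221). The test asked for a limit over 1 in every class, so over these classes together free RNA stays open for FST too. In glia-like cells both lower limits were over 1. This argues against RNA from stroma-like cells as the whole source of FST there, but not in the other classes. For PODXL and NPHS2, lower with VEGF outside podocyte-like cells, the ratio of podocyte genes to PODXL did not differ detectably between classes (chi-square p = 0.329), with a spread of 2.12-fold and 2.14-fold. Free RNA from podocyte-like cells may account for those falls.

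The lower podocyte-like share with VEGF was weighed against 2 technical explanations. With barcodes that share 11 bases merged, the log2 ratio was -1.70 (adjusted p = 0.0360), which argues against beads counted more than once as the whole cause. With each cell thinned to 1000 counts, 605 and 622 shallower cells with VEGF and 728 and 195 without left out, and the cells clustered again, the podocyte-like log2 ratio was -1.98 (adjusted p = 3.49e-05), which argues against depth per cell as the whole cause. The edgeR test of the share set the difference against the spread between wells, and an effect of VEGF165 stays open as a hypothesis.

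Over its 24 genes the endothelial list had a median fold of 4.30 in bulk, more than the ratio of endothelial-like shares in Drop-seq. The first measures RNA and the second counts cells. Over the 12 genes measured in both assays the median log2 ratio was 1.62 in bulk and 0.23 in Drop-seq. The log2 ratio of shares was 1.04. Against the bulk median log2 ratio of 2.10 over 24 genes, the gap was therefore no smaller with genes and measure matched. In libraries A and B the ratio of shares was 2.93, and its upper counting limit of 10.6 lies above the bulk fold, so few cells could account for the gap. Over the genes measured in both assays, the list took 5.55 times as much of the bulk counts as of the Drop-seq counts with VEGF and 2.13 times without. The stroma list gave 7.79 and 8.57. An equal loss of endothelial cells from the suspension would cancel only if other cells gave no counts of the list. They gave some, since CLDN5 was also a leading gene of podocyte-like cluster 3. The difference between 5.55 and 2.13 restates the gap itself and cannot tell an equal loss from a larger one with VEGF. Both stay open.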

How the results depend on the processing

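The merged barcodes, clustering of thinned cells, and list genes in place of clusters for classes other than endothelial were chosen after the data were seen; the cause of the changes below was not tested unless a reason is given.

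With an estimated correlation no list in the whole library passed: adjusted p = 0.147 for podocyte, proximal tubule, mural, muscle, cartilage, melanocyte and endoderm, 0.161 for stroma, 0.190 for endothelial, glia, blood, tip cell and proliferation, 0.248 for pluripotent and immediate early, 0.375 for distal nephron and 0.603 for hypoxia. Within classes adjusted p was 0.379 for proliferation in distal nephron-like, glia-like and podocyte-like cells, for immediate early genes in glia-like, podocyte-like, proximal tubule-like and stroma-like cells and for tip cell genes in neuron-like cells. It was 0.384 for the VEGF and basement membrane lists in stroma-like cells, 0.451 for proliferation in neuron-like and proximal tubule-like cells and 0.644 for immediate early genes in distal nephron-like cells. For hypoxia it was 0.695 in distal nephron-like, 0.636 in glia-like, 0.625 in neuron-like and stroma-like, 0.462 in podocyte-like and 0.722 in proximal tubule-like cells, and in the last 0.479 for basement membrane and 0.729 for mitochondrially encoded genes. With all deposited barcodes the basement membrane list passed (0.0469). Under fry the endothelial, proximal tubule, mural and cartilage lists (fry adjusted p = 0.0446 each) and the melanocyte list (0.0199) passed in the whole library. The other lists did not pass under fry, among them stroma (0.0633), muscle (0.0656), podocyte (0.0671), pluripotent (0.129) and immediate early (0.151).

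With no filter on low counts 956 genes were higher and 674 lower in the whole library, 49 and 28 in distal nephron-like and 72 and 59 in proximal tubule-like cells, and 204 were lower in podocyte-like cells. DESeq2 gave 8 higher and 0 lower in distal nephron-like, 130 and 121 in glia-like, 81 and 69 in neuron-like, 47 and 28 in podocyte-like, 13 and 2 in proximal tubule-like and 101 and 41 in stroma-like cells. With merged barcodes 1 was lower in distal nephron-like, 113 in podocyte-like and 6 in proximal tubule-like cells, and 441 were higher and 178 lower in stroma-like cells. Of the named genes 170 kept their side of the threshold with DESeq2, 46 lost it and 2 gained it, with 0 reversed.

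Among shares, the muscle-like log2 ratio was -0.63 with merged barcodes, -0.68 when thinned cells were clustered and -0.69 at 300 genes. At 1000 genes the distal nephron-like ratio (-0.91) and the stroma-like one (0.71) passed, and no endothelial-like cluster formed. At resolution 0.4 the podocyte-like ratio was -0.52 and the proximal tubule-like one reversed to 0.37, neither passing. The stroma-like ratio passed with 3 list genes (0.62) and with thinning of those (0.71). The endothelial difference was 0.345 points with merged barcodes, 0.722 with 3 list genes and 1.64 with those and merged barcodes. Removing doublets took out only 5 cells and tests nothing.

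In bulk, 5 CPM added gave 422 genes higher and 230 lower, and medians of 1.52 for endothelial, 0.26 for VEGF and 1.09 for tip cell genes. With 0.1 CPM 956 were lower and the endothelial median was 2.36. With total counts only EPCAM (-0.085), NRP1 (-0.053), NRP2 (-0.037) and PGK1 (-0.0286) reversed, and the medians were 1.98 for endothelial, -1.80 for podocyte, 0.22 for VEGF and 0.99 for tip cell genes, since that scaling shifts all genes by -0.13. Against bulk, libraries A and B alone gave r = 0.507 and rho = 0.324, and C and D r = 0.579.

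Leaving out 1 library leaves 1 in its group, assumed to vary like the other group. Whole-library counts ranged from 341 to 1102 higher and 204 to 758 lower. Adjusted p ranged from 0.0186 to 0.0703 for endothelial, 0.0254 to 0.268 for basement membrane, 4.31e-07 to 0.75 for hypoxia, 0.0313 to 0.906 for mitochondrially encoded, 0.0158 to 0.890 for neuron and 7.88e-05 to 0.0757 for tip cell genes. HEY1 ranged from -0.95 to 0.59 and reversed without VEGF replicate 1. Higher and lower counts ranged from 15 to 89 and 1 to 44 in distal nephron-like, 199 to 306 and 126 to 259 in glia-like, 123 to 234 and 98 to 248 in neuron-like, 51 to 326 and 12 to 252 in podocyte-like and 14 to 106 and 2 to 49 in proximal tubule-like cells, and 77 to 139 were lower in stroma-like cells. The proximal tubule-like share ranged from -2.09 to -1.41.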

Other observations

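All tests in this part were chosen after the data were seen. Cells with counts of at least 3 mural list genes were 9.08% ± 0.09 with VEGF and 1.42% ± 0.0298 without, 6.38-fold (edgeR, adjusted p = 3.07e-05, higher in 2 of 2 libraries). These shares count cells that hold list genes, with no background taken off, so free RNA is not excluded from any of them. Such cells were also more frequent for cartilage (2.64% against 0.567%, adjusted p = 0.00227), stroma (26.5% against 17.2%, adjusted p = 0.0315), endothelial (1.45% against 0.725%, adjusted p = 0.0463) and pluripotent genes (0.511% ± 0.425 against 0.0353% ± 0.00233, adjusted p = 0.0132). For pluripotent genes the 2 VEGF libraries differed widely. Cells holding list genes were less frequent for podocyte (14.6% against 30.8%, adjusted p = 0.00249), proximal tubule (0.871% against 2.57%, adjusted p = 0.00259), muscle (0.577% against 2.31%, adjusted p = 0.00227), melanocyte (0.183% against 0.613%, adjusted p = 0.0146) and endoderm genes (0.0176% ± 0.0249 against 0.388% ± 0.0257, adjusted p = 0.00448). For endoderm genes the share with VEGF was near 0 and smaller than its SD. Nephron progenitor, distal nephron, glia, neuron and blood genes did not pass (adjusted p = 0.431, 0.405, 0.381, 0.887 and 0.405).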
